A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

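Chromatin immunoprecipitation followed by sequencing was carried out on Saccharomyces cerevisiae cells taken 4 hr into meiosis, after transfer to potassium acetate sporulation medium. The 12 libraries came from 6 cultures of 3 genotypes: wild type, a bas1 null and an ino4 null. Each genotype had 2 independent cultures, and per the labels each culture gave 1 library with an antibody to histone H3 trimethylated at lysine 4 (H3K4me3) and 1 with an antibody to histone H3, so that the 6 groups had 2 libraries each. Per the labels, formaldehyde crosslinks were followed by digestion of the chromatin with micrococcal nuclease, an enzyme that cuts between nucleosomes.

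Per the submitters' processing notes, BWA 0.7.5a-r405 and the sacCer2 build were used. The 12 deposited files list counts, the whole number of reads at each base position with at least 1 read, not normalized and without a strand. Whether a position is the end or the centre of a read, how reads with several matches were placed and whether repeated reads were removed are not given in the sources used here. Between 22.8% and 66.3% of a library's reads were beyond the first at their position, which also rises with depth. Without molecular identifiers it is not known whether these reads are independent molecules, so counting limits cover counting error only.

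The deposited files carry the opposite antibody in their names to the one in the labels in 12 of 12 samples. Groups were taken from the labels, and each library is called by its label ("labelled H3", "labelled H3K4me3"). The log2 ratio is given as labelled H3 over labelled H3K4me3. Under the file names this is H3K4me3 relative to H3, and under the labels it is H3 relative to H3K4me3. The tests are the ones fixed before the data were examined with the sign turned.

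Reads were summed in 1 kb tiles of the 16 nuclear chromosomes in sacCer2 coordinates. The plan was to count the first 500 bp of genes, with tiles to be used if gene positions could not be placed on the build of the files. The gene table at hand describes another assembly (R64), so it served only for the names of BAS1 and INO4 and their neighbours. Windows laid from that table were computed first and then set aside because the builds differ. No value from them is reported, and the added alternatives and region classes were chosen after they had been seen. The gene lists fixed before the data were examined, the ratio at the 5' ends of genes and gene names for tiles were therefore not analysed here. Of 12029 tiles, 2 adjacent tiles of chromosome XII (459001 to 461000) with over 10 times the median number of reads were set apart. The edgeR filter on low counts (filterByExpr by group) left 11611 tiles. A library had a median of 160 to 1252 reads per tested tile.

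Counts per tile were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, glmQLFit and glmQLFTest), with all 12 libraries in 1 fit of 6 groups. Adjusted p-values are Benjamini-Hochberg values from edgeR unless another tool is named, with a threshold of 0.05, and errors of log2 changes are standard errors (SE). TMM and library-size scaling give relative levels. No spike-in was used here, so a change of the whole genome would not be seen. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so single values per group are given without a test. The rule for named tiles, written for genes before the data were examined and applied to tiles, took the 10 largest rises and the 10 largest falls past the threshold with both mutant cultures beyond both wild-type cultures. Where no tile outside the deleted stretches passed, it took the 5 tiles with the smallest p each way. The tiles over the deleted stretches were always included.

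Region classes (tiles within 10 kb and 10 to 30 kb of a chromosome end, and each chromosome beyond 30 kb from its ends, 18 in all) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. No class of any comparison passed with an estimated correlation, the smallest adjusted p being 0.302. With fry, which asks for a change of a class and not for a difference from other tiles, 2 classes passed, both in ino4 labelled H3: VII (adjusted p = 0.0152, median log2 change 0.01 and mean -0.09) and XV (adjusted p = 0.00757, median -0.02 and mean -0.10). The classes replaced the gene lists after the data were seen. The stretches without reads were located in the libraries themselves, as stretches over 200 bp with 0 reads in the 4 libraries of a genotype and, in each of the other 8, a read density over 0.2 of the median tile. The 4 adjacent ones were joined across the few positions with reads between them. For log2 levels per library a prior count of 2 was added, and each library was centred on its median over tiles beyond 30 kb from the ends.

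The fit was tested on simulated counts drawn from the 11611 tiles, with 200 tiles changed. For the ino4 ratio, 0% of 1.5-fold, 17.9% of 2-fold and 83.3% of 3-fold changes were recovered. The shares were 10.4%, 76.1% and 97.0% for ino4 labelled H3, and 14.9%, 71.6% and 98.5% for ino4 labelled H3K4me3. For the bas1 ratio they were 1.49%, 28.4% and 77.3%. For bas1 labelled H3 they were 19.4%, 77.6% and 98.5%, and for bas1 labelled H3K4me3 2.99%, 58.2% and 97.0%.

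The design text ties 1 library of each antibody to each culture, and culture numbers come from the titles. Deviations from the group means of the 2 libraries of a culture correlated at -0.0327 to 0.357 over tiles in the 3 genotypes, against -0.238 to 0.712 for the other 12 pairs of groups. Among the labelled H3 groups they correlated by replicate number in all 3 pairs (wild type and bas1 0.269, wild type and ino4 0.314, bas1 and ino4 0.712), so libraries of 1 number may share a difference that the independent simulations leave out. Alternatives were library-size scaling without TMM, DESeq2 1.42.0 on the same tiles, no filter on low counts, each position counted at most once per library, the replicate number or the culture as a block, chromosome ends and shifted chromosomes (I, III, VI and XII) left out, and each library left out in turn. The filters of DESeq2 on mean counts and outlying libraries were turned off after they had left tiles of the deleted stretch without an adjusted p, so that the tiles tested stayed the same, which moved the bas1 labelled H3K4me3 count from 192 to 114 and no other. Added after the data were seen were tiles of 500 bp and 2 kb, tiles shifted by 500 bp, and each bas1 culture left out. Also added were 1 wild-type culture per mutant, positions counted once in thinned libraries, and fits of the compared genotypes alone. A smooth trend (lowess span 0.3) on the ratio averaged over all 12 libraries was also removed. That average holds part of any mutant change. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.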

Results

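H3K4me3 marks nucleosomes at the 5' ends of transcribed genes, and in yeast meiosis it is also found around sites of recombination. Its level was measured here beside that of histone H3 in wild-type cells and in nulls of BAS1, which encodes an activator of purine and histidine biosynthesis genes, and of INO4, which encodes an activator of phospholipid biosynthesis genes. The labelled H3K4me3 libraries held 5293407 and 3419792 reads in wild type, 2086398 and 3485296 in bas1 and 7843252 and 6237319 in ino4. The labelled H3 libraries held 6000185 and 7571831 in wild type, 3092046 and 5795946 in bas1 and 17028072 and 16668279 in ino4. Read positions recurred at a spacing of 162 to 166 bp in the 12 libraries, with a minimum at 84 to 95 bp.

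The deleted genes were checked first in every library, by a search of the genome for stretches over 200 bp without reads in the 4 libraries of 1 genotype and covered in the other 8. It found 5, of which 4 lay next to each other on chromosome XI in bas1 and 1 on XV in ino4. On chromosome XI, the chromosome of BAS1 (YKR099W, between UBP11 and SKG1 in the R64 gene table), a stretch of 2361 bp (635598 to 637958, sacCer2) held 0 reads in 3 of the 4 bas1 libraries and 4 reads in the other, against 800 to 2199 reads in each of the 8 libraries of the other genotypes. A count of 0 allows up to 3 reads. On chromosome XV, the chromosome of INO4 (YOL108C, between ZEO1 and YOL107W), a stretch of 319 bp (111506 to 111824) held 0 reads in 4 of 4 ino4 libraries, against 51 to 455 reads in the other 8. The 1 kb to each side was covered in all 12 libraries, with at least 52 reads beside the first stretch and 73 beside the second. The search asks for 0 reads in 1 genotype and coverage in the other 8, but not for a chromosome. Gene positions were not placed on sacCer2, so each stretch is tied to its gene by the chromosome alone. On that ground each genotype label matched the reads in 12 of 12 libraries.

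**Figure D1:**
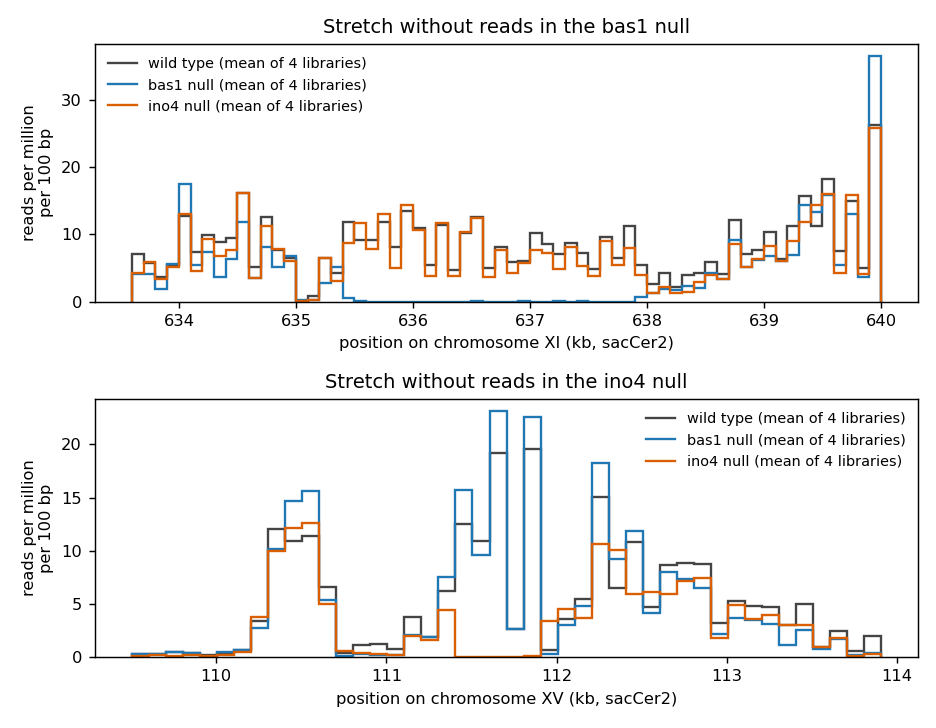
CPM, reads scaled to the library total, in 100 bp bins (y axis) along chromosomes XI and XV (x axis, kb, sacCer2), as the mean of the 4 libraries of each genotype. The bas1 line is at or near 0 from 635598 to 637958 on XI, and the ino4 line is at or near 0 from 111506 to 111824 on XV.

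The antibody labels were checked at chromosome ends, where silenced chromatin is known to hold little H3K4me3. Within 10 kb of the ends the level, relative to tiles beyond 30 kb, was 0.374 ± 0.0921 (SD, n = 6) in the libraries labelled H3 and 0.850 ± 0.142 (SD, n = 6) in those labelled H3K4me3. It was lower in the library labelled H3 in 6 of 6 cultures (two-sided exact permutation p = 0.00216 for 6 libraries against 6, and 0.0313 for exact sign flips within cultures). The libraries labelled H3 were also more uneven over tiles, with a coefficient of variation of 0.613 ± 0.115 (SD, n = 6) against 0.421 ± 0.0997 (SD, n = 6) and a higher value in 6 of 6 cultures (exact permutation p = 0.0152). With each position counted once the unevenness was higher in 4 of 6 cultures (exact permutation p = 0.528), while the level near ends stayed lower in 6 of 6. The level near ends goes against the antibody labels and with the file names. For the ratio of labelled H3 over labelled H3K4me3 below, a rise is a gain of H3K4me3 relative to H3 under the file names and a loss under the labels. A change in the libraries of 1 label is a change of that antigen under the labels and of the other under the file names.

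**Figure D2:**
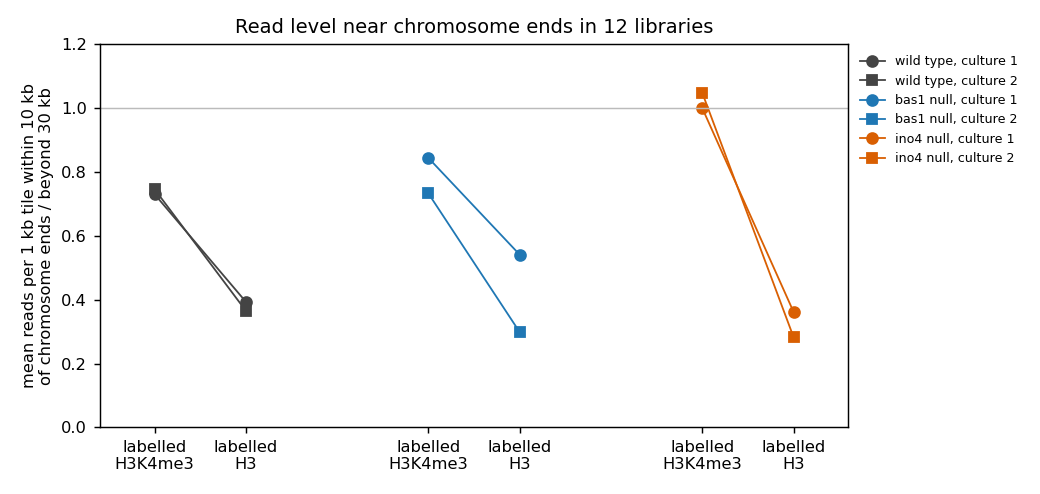
Mean reads per 1 kb tile within 10 kb of chromosome ends over the mean beyond 30 kb (y axis) for each of the 12 libraries (x axis, by genotype and label), with a line joining the 2 libraries of a culture. The libraries labelled H3 lie between 0.283 and 0.541 and those labelled H3K4me3 between 0.730 and 1.05.

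In wild type, the chromosome ends were poorer in the labelled H3 than in the labelled H3K4me3 libraries, and the interior held alternating stretches of both signs. Of the 11611 tiles, 3798 were higher and 3974 lower in labelled H3 over labelled H3K4me3 (edgeR). Under the file names these are tiles rich and poor in H3K4me3 relative to H3, and under the labels the reverse. Of the 232 tiles tested within 10 kb of the ends, 153 were lower and 9 higher, with a median log2 ratio of -1.10 (camera adjusted p = 5.67e-09, and adjusted p = 0.971 with an estimated correlation). Of the 567 tiles 10 to 30 kb from the ends, 261 were lower and 97 higher, with a median of -0.48 (camera adjusted p = 0.0124, and adjusted p = 0.971 with an estimated correlation).

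The longest wild-type runs of adjacent tiles below 0 were 14 tiles at the left end of chromosome VII (1 to 14000, median log2 ratio -1.40) and 14 tiles on XII (349001 to 363000, median -1.44), followed by 12 tiles on XI (535001 to 547000, median -1.29) and 12 on XV (344001 to 356000, median -1.04). The left end of chromosome III (1001 to 12000) formed a run of 11 tiles with a median of -1.63. The longest run above 0 was 9 tiles on XIII (556001 to 565000, median 0.81). Runs of at least 5 tiles numbered 136 below 0 and 49 above 0. Among single tiles, XI 442001 to 443000 (1.70 ± 0.18 SE, adjusted p = 0.000834, edgeR) and VII 494001 to 495000 (1.67 ± 0.16 SE) were among the highest. The lowest included VIII 91001 to 92000 (-2.80 ± 0.49 SE, with 43 and 32 reads labelled H3K4me3 and 7 and 10 labelled H3) and XII 5001 to 6000, where 14 and 11 reads labelled H3K4me3 stood against 1 and 4 labelled H3. The count of 7772 fell to 5141 without the wild-type library labelled H3 of culture 2, and was 9782 in a fit of the wild-type libraries alone.

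In the bas1 null, no tile passed the threshold for a change of the ratio against wild type. Outside the deleted stretch, the tiles with the smallest p upward were V 277001 to 278000 (log2 1.35 ± 0.21 SE, adjusted p = 0.561, edgeR) and XVI 590001 to 591000 (1.25 ± 0.21 SE, adjusted p = 0.585). Those downward were XII 325001 to 326000 (-1.18 ± 0.25 SE) and XII 845001 to 846000 (-0.90 ± 0.21 SE), each with an adjusted p of 1.00 (edgeR). An H3K4me3 gain relative to H3 would be upward under the file names and downward under the labels. The count was 0 with edgeR, with 375 tiles at an unadjusted p under 0.05, and 7 with DESeq2. It was 1370 without the bas1 library labelled H3 of culture 1 and 2 without that of culture 2. These 2 libraries correlated over tiles at 0.854 against 0.931 to 0.984 for the pairs of the other 5 groups.

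By chromosome, I, III, VI, IX and XII passed the threshold in bas1 labelled H3K4me3 with camera at its preset correlation, and none passed with an estimated correlation. In the labelled H3K4me3 libraries the median level of chromosome I beyond 30 kb from its ends was 0.39 ± 0.06 (log2, SD, n = 2) in bas1 against 0.08 ± 0.01 (SD, n = 2) in wild type, and the tiles of chromosome I had a median change of 0.31 (camera adjusted p = 2.63e-14, and adjusted p = 0.594 with an estimated correlation). For III the median change was 0.19 (camera adjusted p = 6.55e-09, and adjusted p = 0.594 with an estimated correlation), for VI 0.12 (camera adjusted p = 0.0172, and adjusted p = 0.661 with an estimated correlation) and for IX 0.08 (camera adjusted p = 0.0451, and adjusted p = 0.594 with an estimated correlation). Chromosome XII had a median change of -0.13 (camera adjusted p = 0.000374, and adjusted p = 0.661 with an estimated correlation), and its level in the bas1 cultures (0.07 and 0.18) overlapped that in wild type (0.17 and 0.32). The ratio had a median change of -0.19 on I (camera adjusted p = 9.58e-07), -0.17 on III (9.83e-05) and 0.16 on XII (5.32e-06), each with adjusted p = 0.791 with an estimated correlation. These shifts came mostly from bas1 culture 2 (-0.45, -0.30 and 0.27 on I, III and XII), with -0.02, -0.07 and 0.02 in culture 1. In the libraries labelled H3 the 2 bas1 cultures lay on opposite sides of wild type on chromosome I, at 0.37 and -0.40.

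**Figure D3:**
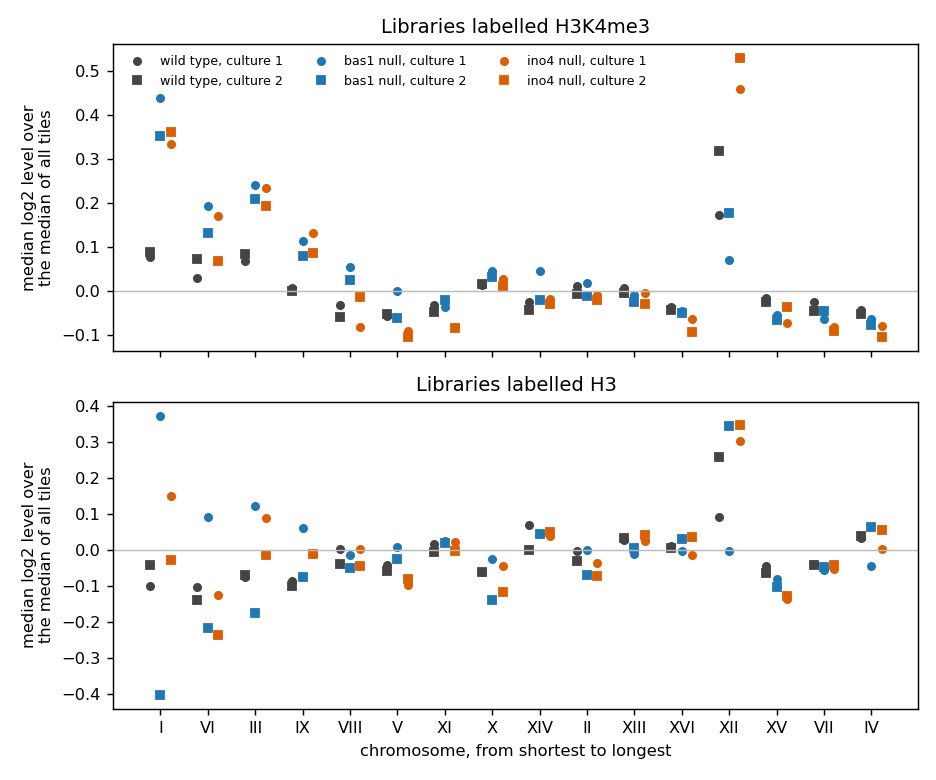
Median log2 level of the tiles beyond 30 kb from the ends of each chromosome over the median of all such tiles (y axis), for chromosomes ordered by length (x axis), with 1 point per library. In the libraries labelled H3K4me3 both mutants lie above wild type on I (0.39 in bas1 and 0.35 in ino4 against 0.08), and the points of the bas1 cultures in the libraries labelled H3 part on I (0.37 and -0.40).

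In the bas1 libraries labelled H3K4me3, 3 tiles passed the threshold, and all 3 lie over the deleted stretch (XI 635001 to 638000, where the middle tile had 0 and 2 reads in bas1 against 545 and 314 in wild type). Outside it the count was 0 with edgeR, with 1481 tiles in all at an unadjusted p under 0.05, and DESeq2 called 114 tiles in all, 93 higher and 21 lower, and 192 with its default filters, all higher. The largest upward change among the 5 tiles with the smallest p was at IV 453001 to 454000 (0.82 ± 0.14 SE, adjusted p = 0.170, edgeR), and the largest downward at XIII 520001 to 521000 (-0.89 ± 0.16 SE, adjusted p = 0.170). The count was 452 and 482 without the bas1 library labelled H3 of culture 1 or 2. In the bas1 libraries labelled H3, the same 3 tiles of XI fell and 3 others rose: XVI 590001 to 591000 (1.23 ± 0.15 SE, adjusted p = 0.0135), XVI 226001 to 227000 (1.23 ± 0.16 SE, adjusted p = 0.0271) and VI 168001 to 169000 (1.15 ± 0.16 SE, adjusted p = 0.0430, edgeR). That count of 6 was 4865 and 1242 without the bas1 library labelled H3 of culture 1 or 2, and 3 without any 1 wild-type library, without either ino4 library labelled H3K4me3 and in the fit of bas1 and wild type alone. DESeq2 called 441.

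In the ino4 null, the libraries labelled H3 changed widely, and the change followed the wild-type ratio. Relative to wild type 995 tiles rose and 1801 fell (edgeR), a split of 444 and 2151 without TMM, which moved the median of all tiles from 0.02 to -0.11. DESeq2 called 901 higher and 2539 lower. Of the 2794 tiles outside the deleted stretches, 2650 moved in the direction of their wild-type log2 ratio, and over all tiles the change correlated with that ratio at 0.699 (tiles are not independent replicates). With each position counted once these values were 2378 and 0.246, and 2650 and 0.686 in thinned libraries with each position counted once. Tiles high in labelled H3 over labelled H3K4me3 in wild type thus became higher and low ones lower, which is a wider spread of H3K4me3 under the file names and of H3 under the labels. Removal of a smooth trend on the ratio averaged over all 12 libraries left 264 of the 2794 tiles past the threshold.

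Of the 20 named tiles with the largest changes in ino4 labelled H3, 13 lay within 30 kb of a chromosome end, against 162 of the 2774 other called tiles and 799 of all 11611 tested. At 4 of the 13 both wild-type libraries labelled H3 had fewer than 10 reads. At VI 2001 to 3000, wild type had 4 and 2 reads and ino4 344 and 418 (adjusted p = 0.00114, edgeR), and the labelled H3K4me3 libraries rose there too, from 5 and 2 reads to 142 and 181 (adjusted p = 0.00427). XVI 931001 to 932000 rose from 20 and 27 reads to 512 and 486 (3.21 ± 0.32 SE, adjusted p = 0.00463), and II 221001 to 222000, far from an end, from 24 and 37 to 318 and 295 (2.13 ± 0.30 SE, adjusted p = 0.0141). IX 434001 to 435000 had 10 and 14 reads in wild type and 0 in both ino4 libraries. IV 645001 to 646000 fell from 67 and 118 reads to 36 and 39 in deeper libraries (-2.47 ± 0.39 SE, adjusted p = 0.0141). The longest run of lower tiles spanned IV 1371001 to 1381000 (10 tiles, median -1.02), followed by II 517001 to 526000 (9 tiles, -0.94) and XI 536001 to 545000 (9 tiles, -1.02). Runs of at least 5 tiles numbered 31 lower and 2 higher.

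The ino4 count in labelled H3 moved with the libraries in the fit, including bas1 libraries that the comparison does not use. It was 1 and 0 without the wild-type library labelled H3 of culture 1 or 2, and 3 without the ino4 library labelled H3 of culture 2. It was 5690 and 5856 without the bas1 library labelled H3 of culture 1 or 2, and 1510 to 1520 without any 1 wild-type or ino4 library labelled H3K4me3. With each position counted once it was 9 (7 higher and 2 lower), and the median size of the change of the 2794 tiles was 0.26 against 0.71. Such counts saturate in deep libraries, and with thinned libraries the count was 1778 and the size 0.61. In the fit of ino4 and wild type alone the count was 5844, which included the 2796.

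The ratio in ino4 changed past the threshold at 1 tile, XII 325001 to 326000 (log2 -2.13 ± 0.24 SE, adjusted p = 0.0303, edgeR), where labelled H3 lost ground to labelled H3K4me3. The same tile was among those with the smallest p downward in the bas1 ratio, against the same wild-type cultures. In ino4, 4037 tiles had an unadjusted p under 0.05. DESeq2 called 2307 tiles, the culture as a block 1608, the replicate number as a block 1940, and the fit of ino4 and wild type alone 5248 (2118 higher and 3130 lower). It was 5037 and 5109 without the bas1 library labelled H3 of culture 1 or 2, 2409 without the ino4 library labelled H3 of culture 1, and 0 without any 1 of the other 9 libraries. The SD of the log2 ratio over tiles was 1.13 and 1.42 in the ino4 cultures against 0.713 and 0.786 in wild type, and 0.622 and 1.07 in the bas1 cultures. Within 10 kb of the ends the median change was -0.83 (camera adjusted p = 7.28e-06, and adjusted p = 0.954 with an estimated correlation), with -0.55 in culture 1 and -1.02 in culture 2. With the trend on the ratio averaged over all 12 libraries removed it was 0.09.

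**Figure D4:**
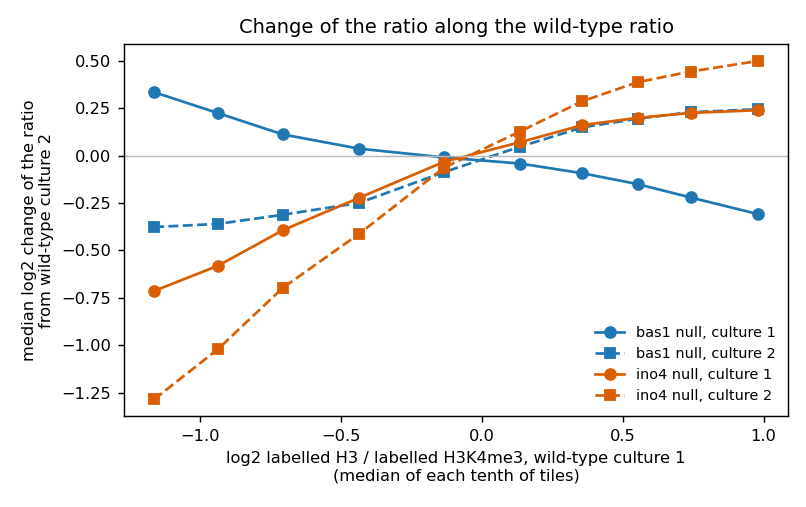
Median change of the log2 ratio of labelled H3 over labelled H3K4me3 from wild-type culture 2 (y axis) in 10 bins of equal size of the tiles ordered by the ratio in wild-type culture 1 (x axis), with 1 line per mutant culture. The lines of both ino4 cultures and of bas1 culture 2 rise and that of bas1 culture 1 falls, with slopes over tiles (the mean of both ways of using the 2 wild-type cultures) of 0.451, 0.816, 0.337 and -0.223.

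In the ino4 libraries labelled H3K4me3, 2 tiles rose: VI 2001 to 3000 (above) and V 5001 to 6000 (log2 1.42 ± 0.18 SE, adjusted p = 0.0464, edgeR). With each position counted once neither passed, and 1 tile was lower. The level near chromosome ends was 1.02 ± 0.0339 (SD, n = 2) against 0.738 ± 0.0111 (SD, n = 2) in wild type, and 0.684 against 0.615 with each position counted once. Tiles within 10 kb of the ends had a median change of 0.40 (camera adjusted p = 5.69e-09, and adjusted p = 0.426 with an estimated correlation), which was 0.15 with the ratio trend removed. Chromosome I had a median change of 0.27 (camera adjusted p = 2.08e-07, and adjusted p = 0.426 with an estimated correlation), III of 0.15 (camera adjusted p = 0.00580, and adjusted p = 0.448 with an estimated correlation), IX of 0.11 (camera adjusted p = 0.0420, and adjusted p = 0.426 with an estimated correlation) and XII of 0.27 (camera adjusted p = 3.16e-13, and adjusted p = 0.388 with an estimated correlation). Medians on I, III, IX and XII were also above 0 in ino4 labelled H3, at 0.19, 0.15, 0.09 and 0.16. None of those passed with camera. The ino4 ratio had medians of -0.10, 0.06, 0.02 and -0.07 there, and none passed with camera. The rises on these chromosomes were thus not particular to labelled H3K4me3. The tile over the deleted stretch on XV (111001 to 112000, with covered flanks) had a log2 change of -2.49 ± 0.35 SE (adjusted p = 0.0803) in labelled H3K4me3 and fell by 2.70 ± 0.31 SE (adjusted p = 0.00678, edgeR) in labelled H3. Without TMM the median of all tiles in labelled H3K4me3 moved from 0.02 to -0.10, and the changes by chromosome are relative to it. At an unadjusted p under 0.05 there were 1501 tiles. DESeq2 called 142 and the fit of ino4 and wild type alone 1178. The count was 1174 and 1243 without the bas1 library labelled H3 of culture 1 or 2, 0 without either wild-type library labelled H3K4me3, and 1 without any 1 of the other 8.

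Chromosome XII carried a broad rise around the ribosomal DNA array in all 3 genotypes. Over 300001 to 600000 (261 tiles) the log2 level above the median of tiles beyond 30 kb from the chromosome ends was 0.68 ± 0.32 (SD, n = 2) in wild type, 0.42 ± 0.31 (SD, n = 2) in bas1 and 1.35 ± 0.12 (SD, n = 2) in ino4 for labelled H3K4me3. For labelled H3 it was 0.55 ± 0.27 (SD, n = 2), 0.54 ± 0.54 (SD, n = 2) and 1.09 ± 0.11 (SD, n = 2). Both ino4 cultures lay above all 4 cultures of the other genotypes in the libraries of each label.

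**Figure D5:**
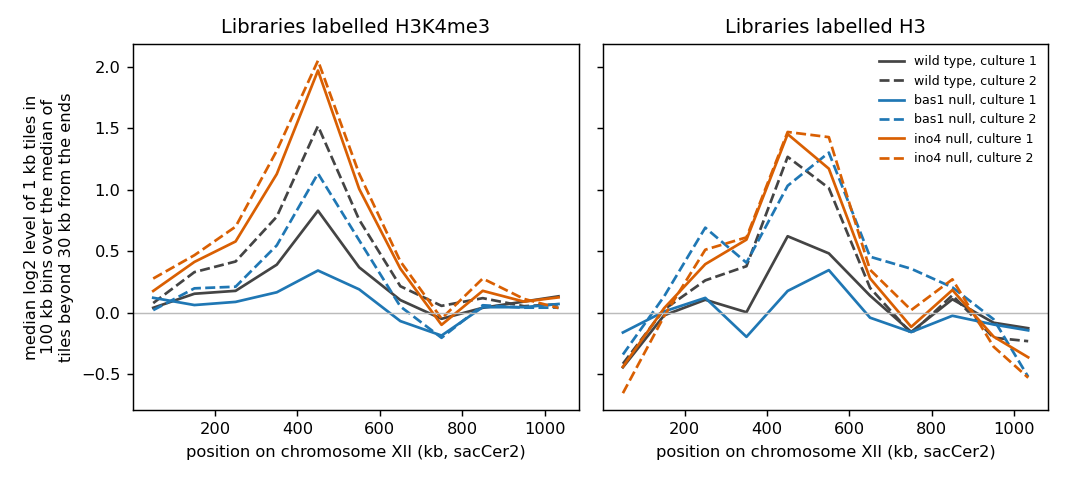
Median log2 level of the 1 kb tiles in 100 kb bins of chromosome XII over the median of the tiles beyond 30 kb from all chromosome ends (y axis) by position (x axis, kb, sacCer2), with 1 line per library. The level peaks between 400001 and 500000 in labelled H3K4me3, from 0.34 in bas1 culture 1 to 2.05 in ino4 culture 2.

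The 2 mutants were compared with each other and for shared changes. A test of the difference between them passed the threshold for the ratio at 1 tile, V 277001 to 278000 (log2 -2.30 ± 0.21 SE for ino4 minus bas1, adjusted p = 0.00321, edgeR), with 2963 tiles at an unadjusted p under 0.05. DESeq2 called 1026. The count was 1152 and 5164 without the bas1 library labelled H3 of culture 1 or 2, 1239 without the ino4 library labelled H3 of culture 1, 0 without either bas1 library labelled H3K4me3, and 0 in the fit of the mutants alone, where that tile had an adjusted p of 0.108. The ratio was also lower in ino4 than in bas1 within 10 kb of the ends (median -0.87, camera adjusted p = 2.67e-09) and on XII (median -0.28, 1.21e-06), and higher on III (median 0.16, 0.0352), each with adjusted p = 0.784 with an estimated correlation. With the ratio trend removed these medians were -0.03, -0.24 and 0.16.

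The changes of the 2 mutants against the shared wild-type libraries correlated over 11607 tiles at 0.456 for the ratio, with a mean of 0.497 in 50 simulations of unchanged mutants, which took the libraries as independent. Their covariance was 0.0786 against a simulated 0.0506. For labelled H3 the correlation was 0.654 against 0.499 and the covariance 0.103 against 0.0248, with 3 shared calls against 0.257 for independent lists of rises. These 3 are all the bas1 rises outside the deleted stretch. Both lists rest on the same wild-type libraries and are not independent, so the 0.257 cannot show an excess. For labelled H3K4me3 the correlation was 0.172 against 0.495 and the covariance 0.0171 against 0.0259. The 2 wild-type cultures could not be split into sets of at least 2 each. With 1 wild-type culture per mutant, so that none was shared (log2 levels of single libraries), the correlation was 0.480 with culture 1 for bas1 and 0.270 with culture 2 for bas1 for the ratio, 0.679 and 0.511 for labelled H3, and 0.165 and 0.00643 for labelled H3K4me3. The covariance was 0.0826 and 0.0499, 0.104 and 0.0814, and 0.0157 and 0.000698, so the values depended on the wild-type culture taken. For the ratio the correlation was -0.16 without the bas1 library labelled H3 of culture 2.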

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

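Of the tests below, the thinning of the libraries for depth was set out before its result was seen, and the other tests were chosen after the patterns had been seen. Groups of 2 libraries were too small for a test of single outlying libraries. The difference at V 277001 to 278000 was found because a test of the 2 mutants against each other passed the threshold (log2 -2.298, adjusted p = 0.00321, edgeR). Its ratio was above that of both wild-type cultures in both bas1 cultures and below it in both ino4 cultures. Over the 23 alternatives the difference ranged from -2.48 to -1.44 and the adjusted p from 3.73e-18 (DESeq2) to 0.108 (edgeR, the fit of the mutants alone). The count of such tiles was 0 without either bas1 library labelled H3K4me3 (culture 1 or 2). No explanation of it was tested.

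Reads outside the tiles compared were above the wild-type level in some libraries. Mitochondrial reads made up 0.0209% of the ino4 library labelled H3K4me3 of culture 1, 0.003813% of the bas1 library labelled H3 of culture 2, and 0.007634% and 0.001488% of the ino4 libraries labelled H3 of cultures 1 and 2, against at most 0.00189% in wild type for labelled H3K4me3 and 0.000950% for labelled H3. The 2 tiles of chromosome XII set apart (459001 to 461000) held 12.6% and 14.42% of the reads of the ino4 libraries labelled H3K4me3 and 7.948% of the bas1 library labelled H3K4me3 of culture 1, against 5.91% and 7.59% in wild type. They held 3.62% of the bas1 library labelled H3 of culture 1, against 1.29% and 1.97% in wild type. In the other libraries they held less than in wild type: 5.74% of the bas1 library labelled H3K4me3 of culture 2, 0.403% of the bas1 library labelled H3 of culture 2, and 1.22% and 0.214% of the ino4 libraries labelled H3. No explanation of these shares was tested.

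The 1st pattern was the lower level near chromosome ends in the libraries labelled H3. Had the labels been right, the libraries labelled H3K4me3 would have had the lower level, but their mean was 0.8496 against 0.3737 for those labelled H3. Repeated reads at single positions were argued against, since with each position counted once the means still differed by 0.2303, more than the SD of either. The values are in line with an exchange of the antibody labels, as the file names have it, in 6 of 6 cultures. The antibody behind each single library stays open.

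The 2nd pattern was the wide change of ino4 in the libraries labelled H3. For depth, the reads of each library in the tested tiles were thinned to the smallest of its label (2979653 reads for labelled H3 and 1919879 for labelled H3K4me3). The median size of the log2 change of the 2794 tiles was then 0.6974 against 0.71. Thinning keeps the expected share of reads of each tile, so this size could not decide on depth. At equal depth 1653 of the 2794 tiles still passed, so unequal depth alone did not give those calls, while the others no longer passed. Repeated reads at single positions stay open. For these a separate thinning took whole libraries to the smallest total of the label (3092046 reads for labelled H3 and 2086398 for labelled H3K4me3). With each position counted once the median size was 0.26 (median SE 0.13) in libraries of unequal depth, where such counts saturate. It was 0.6122 in the libraries of the separate thinning. There repeated reads made up 30.7% and 31.8% in ino4 labelled H3 against 26.5% and 27.8% in wild type. They made up 30.4% and 33.6% in bas1 labelled H3, so the higher share was not particular to ino4. With the trend on the ratio removed the median size fell to 0.2267 and the median SE from 0.18 to 0.12, so that most calls ended because the change shrank, but such a removal must shrink any change that follows the ratio, and a difference between libraries in how unevenly reads lie and the ino4 genotype both stay open. The slopes of the 2 bas1 cultures on the wild-type ratio differed by 0.56 where the mean ino4 slope was 0.633. By replicate number the ino4 slope exceeded that of bas1 by 0.674 and 0.479. However, 2 pairs allow no exact two-sided p below 0.5, and the labels do not say that the numbers pair cultures of different genotypes.

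The 3rd pattern was the 20 largest ino4 changes in labelled H3. A change in the signal of 1 antibody alone was argued against for the 20 as a set. At 19 of the 20 tiles the libraries labelled H3K4me3 had a log2 change in the same direction of more than 2 SE. That limit is unadjusted, and of the 20 only VI 2001 passed the threshold in those libraries. Single tiles other than it are thus not settled. The direction was the same at 20 of 20 tiles, against 1142 of the 2774 other called tiles (two-sided Fisher's exact p = 2.177e-08, tiles not being independent), and 17 of the 20 still passed with the trend removed. A difference in DNA between the ino4 and wild-type cultures at these tiles stays open. Labelled H3 changed more than labelled H3K4me3 by over 2 SE at 7 of the 20, which decides nothing, as the tiles were chosen by their change in labelled H3 and some had wild-type counts near 0.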

How the results depend on the processing

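Tiles of other sizes or positions, removal of the ratio trend, omission of a bas1 culture, fits of the compared genotypes alone, 1 wild-type culture per mutant, the setting of the DESeq2 filters and positions counted once for the label check were chosen after the data were seen, and the other alternatives were planned. Whole genes, other gene windows, a shift of reads and the gene lists were not run, as they need gene positions on the build of the files. Where a library was left out of a group, the lone library was assumed to vary like the others. Causes were not tested except where stated. Tiles of 500 bp and 2 kb change the number tested (23044 and 5869).

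The 7772 wild-type tiles became 14980 with 500 bp and 3412 with 2 kb tiles, and 5141 to 9042 with 1 library left out. For the bas1 ratio 0 became 7 with DESeq2, 6 with the trend removed, 222 without bas1 culture 1, and 0 to 1370 with 1 library left out.

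For the ino4 ratio 1 became 0 without TMM, with positions counted once, with 2 kb tiles and with shifted tiles. It became 2307 with DESeq2, 1940 with the number and 1608 with the culture as a block, 758 without ends and shifted chromosomes, 5 with the trend removed, 5262 and 5325 without bas1 culture 1 or 2, 5248 with the compared genotypes alone, and 0 to 5109 with 1 library left out. For ino4 against bas1 1 became 2 without TMM, without ends and with 2 kb tiles, 1026 with DESeq2, 354 and 4251 without bas1 culture 1 or 2, 0 with the mutants alone, and 0 to 5164 with 1 library left out.

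For bas1 labelled H3K4me3, 3 became 114 with DESeq2 and 192 with its default filters, which left the other counts of DESeq2 unchanged, 1 without ends and with 2 kb tiles, 5 with 500 bp tiles, 827 without bas1 culture 2, and 3 to 482 with 1 library left out. For ino4 labelled H3K4me3, 2 became 142 with DESeq2, 1 with positions counted once (lower, where both had been higher) and 1 with 2 kb tiles, 8 with the number as a block, 0 without ends, 28 with the trend removed, 1278 and 1319 without bas1 culture 1 or 2, 1178 with the compared genotypes alone, and 0 to 1243 with 1 library left out.

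For bas1 labelled H3, 6 became 3 without TMM and with the compared genotypes alone, 441 with DESeq2, 13 without a filter, 104 with positions counted once, 10 with the number as a block, 179 with the trend removed, 22 with 500 bp tiles, 2 with shifted tiles, 4982 and 1471 without bas1 culture 1 or 2, and 3 to 4865 with 1 library left out. For ino4 labelled H3, 2796 became 9 with positions counted once, 438 with the trend removed, 4955 with 500 bp and 1151 with 2 kb tiles, 5858 and 6014 without bas1 culture 1 or 2, 5844 with the compared genotypes alone, and 0 to 5856 with 1 library left out.

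With positions counted once, the unevenness and the level near ends in labelled H3K4me3 became 0.2937 and 0.6154 in wild type, 0.3294 and 0.6459 in bas1 and 0.3835 and 0.6839 in ino4. In labelled H3 they became 0.309 and 0.412 in wild type and 0.3373 and 0.4093 in ino4, and the unevenness 0.4154 in bas1. The correlation of the mutants' ratio changes (0.456) became 0.4436 with DESeq2, 0.5878 with positions counted once, 0.4746 and 0.4759 with the number or culture as a block, 0.511 without ends, 0.4089 with 2 kb tiles, 0.3749 with 1 wild-type culture per mutant, 0.6437 without bas1 culture 1 and -0.1764 without culture 2, and ranged from -0.1627 to 0.6166 with 1 library left out.

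Of 1545 comparisons of 71 named-tile values, 590 with planned or added alternatives and 686 with 1 library left out kept direction and side of the threshold, 59 and 44 passed it newly, 32 and 114 no longer passed, and 12 and 8 changed sign. Every change of sign was in tiles over the deleted stretches, at values not past the threshold. In the bas1 ratio XI 636001 became 0.6367 without bas1 culture 2 and 0.6342 without its labelled H3K4me3 library, XI 637001 became 1.6849, 1.2145 and, without its labelled H3 library, 0.183, and XV 111001 became -0.6151 and, without its labelled H3 library, -0.6082. With 1 library left out these 3 tiles ranged from -4.4294 to 0.6342, from -0.7506 to 1.2145 and from -0.6082 to 0.6163. In the ino4 ratio XI 637001 became 0.0564 with the trend removed, and XV 111001 became 0.5499 with positions counted once and 0.0049 without the ino4 library labelled H3K4me3 of culture 1 (lowest with 1 left out -0.3705). In ino4 labelled H3K4me3 XI 635001 became -0.1053 without TMM, -0.1543 with positions counted once, -0.0104 without the wild-type library of culture 2 and -0.0471 without the ino4 library of culture 1 (highest 0.078), and XI 637001 became -0.0409 without TMM and -0.1479 with the trend removed. In labelled H3 XV 111001 in bas1 became -0.4938 without culture 2 or its library (highest with 1 left out 0.7082), and XI 635001 in ino4 became -0.0261 without TMM and -0.0538 with positions counted once.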

Other observations

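The level of a chromosome in labelled H3K4me3 fell with its length. Over the 15 chromosomes other than XII, Spearman's rho between level and length was -0.524 and -0.504 in the wild-type cultures, -0.927 and -0.851 in bas1 and -0.530 and -0.760 in ino4. In labelled H3 it was 0.657 and 0.611 in wild type, -0.832 and 0.654 in bas1 and -0.268 and 0.30 in ino4. Chromosomes are not independent replicates, and these values were chosen after the data were seen.

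The 2 tiles of XII set apart held a larger share of reads in labelled H3K4me3 than in labelled H3 in 6 of 6 cultures (exact sign-flip p = 0.0313, the smallest that 6 cultures allow). In every library these reads lay at only 982 to 1010 positions, although their number ran from 23368 to 988187. With each position counted once the shares were 0.0170% to 0.0620%. Such counts are saturated here and cannot tell whether the difference rests on repeated reads. The share was 6.75% ± 1.19 (SD, n = 2) against 1.63% ± 0.477 (SD, n = 2) in wild type, 6.85% ± 1.56 against 2.01% ± 2.27 in bas1 and 13.5% ± 1.29 against 0.719% ± 0.714 in ino4.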
